A study of Homo sapiens with 8 samples.

How the data were processed

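Binding of BCL11B, a zinc finger transcription factor needed for T cell commitment, was measured by chromatin immunoprecipitation and sequencing in cells of the human thymus. Per the labels, CD34+ cells, which include the early T cell progenitors, and CD34- cells, which are mostly later thymocytes, were separated on magnetic beads. The CD34+ fraction was over 85% pure. Each cell type had 2 biological replicates. In each cell type 1 replicate came from a pool of 2 thymuses and the other from a further thymus. Per the labels, 19000000 to 29000000 CD34+ cells or 60000000 CD34- cells were fixed in 1% formaldehyde for 10 min and their chromatin was cut with micrococcal nuclease to about 150 bp. Chromatin was then incubated with 1 µg of an antibody to BCL11B or of an isotype control, and libraries made from 5 ng of DNA were read as 75 bp pairs. The 8 samples were therefore 4 immunoprecipitates and 4 isotype controls.

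Reads were aligned with Bowtie2 2.2.6 to hg19 and peaks were called with MACS2 2.1.0, per the submitters' processing notes. Which control was set against which immunoprecipitate, the peak caller's settings and any removal of duplicate reads are not given in the sources used here. The deposited data used here were 4 peak lists, 1 per immunoprecipitate, called by the authors in each library separately and not on pooled replicates. Control signal was not analysed here outside the peak lists. The authors' lists gave for each peak a position, a summit offset in bp from the peak start and a whole-number score. They also gave the authors' fold enrichment, a ratio of the summit pileup to the local background, each with 1 added. The remaining deposited values were the −log10 p-value and −log10 q-value of each summit from the authors' peak caller. The score was read but not used for ranking. These folds and −log10 q-values are the authors' own and were used only to describe, rank or filter peaks within a list.

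Peaks on chromosomes 1 to 22 and X were kept, and 37 peaks elsewhere were left out. The number of reads per library was not in the sources used here. The authors' fold and −log10 p-value of a peak were solved together for a whole-number summit pileup (overlapping fragments) and a local background, under a Poisson model and with a background of at least 0.5. At least 99.97% of the peaks of each list were solved within 0.001 of the deposited −log10 p-value. The lowest local background of a list was taken as its genome background, a measure of depth times fragment length. On 5000 simulated peaks the pileup was recovered in 100%, and the background within 1% in 100%.

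Overlap was the share of peaks of one list that shared at least 1 bp with a peak of another, for the 12 ordered pairs of lists. It was set against 1000 random placements of the first list within the same chromosomes, in a one-sided permutation test with Benjamini-Hochberg adjustment. For counts across libraries, all 4 lists were merged wherever peaks overlapped by 1 bp or more, and each merged region was scored for a peak in each library. A region was called reproducible in a cell type when both of its libraries had a peak there. Strength was the percentile of the −log10 q-value within a list, averaged over the 2 libraries of the cell type, and reproducible regions were divided into 10 equal groups by it. Peaks of 2 sets of regions within a list were compared by two-sided permutation tests with 100000 permutations, on the mean log10 of the −log10 q-value and on the mean width. Intervals are exact Clopper-Pearson 95% intervals. P-values and intervals cover placement and counting of peaks within these libraries, not the spread between thymuses. Values per library were compared between cell types by two-sided exact permutation tests, whose smallest p with 2 libraries against 2 is 0.333. No parametric test was run on so few values.

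The regions named were the 10 with the highest mean percentile of −log10 q in each of 3 sets: a peak in all 4 libraries, in both CD34+ libraries only, or in both CD34- libraries only. Regions wider than 5 kb were left out. This rule, the overlap tests, the region counts and most alternatives were fixed before the data were examined. The recovery of pileups, the groups of strength, the comparisons within a list and the exact tests of values per library were chosen afterwards. The alternatives were a −log10 q of at least 5, a fold of at least 6.40 (the median of the shortest list), and lists cut to the 7617 strongest peaks. Further ones were an overlap of at least 50% of the shorter peak, peaks within 500 bp taken as overlapping, removal of peaks wider than 5 kb or with a pileup above a high percentile of their library, and leaving out each library in turn. The gene annotation at hand was of another genome build, so coordinates are given without genes. The planned tests of location relative to genes, of 17 gene lists and of 20 motifs were not run.

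Overlap code was checked on peaks placed at known positions. Of 8498 simulated peaks, 58.8% were placed on peaks of another list and 59.3% were found to overlap it. Merging gave the simulated count for 15 of 15 combinations of libraries under each of 3 overlap rules. In 50 simulations of independent misses that depended on strength, 4 gave a p of 0.05 or less. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.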

Results

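BCL11B binding was mapped in CD34+ and CD34- cells of the human thymus, in 2 biological replicates of each. The design asks how the sites bound by BCL11B differ between the fraction that holds early progenitors and the fraction of later thymocytes. Each replicate gave 1 list of peaks called over background. All positions are in hg19, and the genes at these positions were not analysed here.

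BCL11B peaks were more numerous and wider in CD34- cells. CD34- replicates 1 and 2 had 15865 and 20499 peaks, and CD34+ replicates 1 and 2 had 8498 and 7617. The mean was 18182 ± 3277 (SD, n = 2) in CD34- cells and 8057.5 ± 623 (SD, n = 2) in CD34+ cells. Both CD34- lists were longer than both CD34+ lists, by 1.87 times in replicate 1 and 2.69 times in replicate 2 (two-sided exact permutation p = 0.333, the smallest that 2 against 2 allow). Peaks covered 9184 and 13357 kb in the CD34- libraries and 3765 and 3139 kb in the CD34+ libraries. The median peak width was 461 and 508 bp in CD34- cells against 354 and 332 bp in CD34+ cells.

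The only measure of depth at hand was the recovered genome background, depth times fragment length. It was 1.13 and 1.03 fragments in CD34+ replicates 1 and 2, and 1.16 and 1.101 in CD34- replicates 1 and 2. The median peak had a summit pileup of 14 and 15 fragments in the CD34+ libraries and of 18 and 20 in the CD34- libraries. The local background was above the genome background at 90.8% and 92.4% of the peaks of replicate 2 of CD34+ and CD34- cells. In replicate 1 these shares were 44.8% and 69.6%. The weakest peak in each list had a −log10 q between 2.01 and 2.099.

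Replicates and cell types shared most of the sites of the shorter lists. Of the CD34+ replicate 2 peaks, 67.8% (95% interval 66.7 to 68.9%) overlapped a CD34+ replicate 1 peak, and 93.5% overlapped a CD34- replicate 2 peak. Of the CD34+ replicate 1 peaks, 60.3% overlapped CD34+ replicate 2 and 83.7% overlapped CD34- replicate 1. Between the CD34- libraries, 86.9% of the replicate 1 peaks overlapped replicate 2, and 64.7% of the replicate 2 peaks overlapped replicate 1. In each of the 12 ordered pairs the overlap exceeded that of all 1000 random placements (permutation p = 0.001, adjusted p = 0.001, the smallest these placements can give). Placement was uniform between the first and last peak of each chromosome. These p-values therefore do not show that the shared sites are particular to BCL11B.

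Part of these differences follows from list length. When each list was reduced to its 7617 strongest peaks, the overlap was 75.2% between the CD34- replicates and 64.7% between the CD34+ replicates. Across cell types it ranged from 63.7% to 68.8%. The value for the CD34+ replicates lay within that range.

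**Figure D1:**
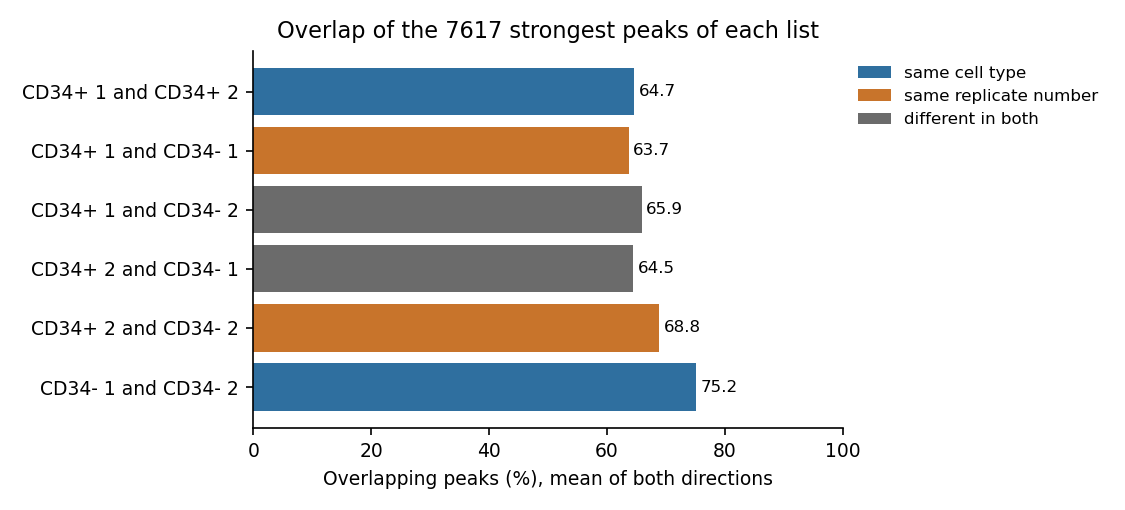
Overlap (%, x axis) of the 7617 strongest peaks of each list for the 6 pairs of libraries (y axis), as the mean of both directions. Bars are coloured by whether the pair shares a cell type, a replicate number or neither, and the CD34- pair has the highest value, 75.2%.

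In the whole lists, nearly all reproducible CD34+ sites were also bound in CD34- cells, while many CD34- sites had no CD34+ peak. The 4 lists merged into 23113 regions, of which 5032 were reproducible in CD34+ cells and 12838 in CD34- cells. Leaving out CD34+ replicate 2 gave 7861 CD34+ regions and leaving out CD34- replicate 1 gave 20413 CD34- regions, since the remaining library then defined the cell type. A peak in all 4 libraries was found at 4734 regions, and at 2093 with a fold of at least 6.40. These were 94.1% (95% interval 93.4 to 94.7%) of the reproducible CD34+ regions and 36.9% (36.0 to 37.7%) of the reproducible CD34- regions. Another 24.5% of the CD34- regions had a peak in 1 CD34+ library. CD34- cells alone had 4957 reproducible regions with no CD34+ peak, and CD34+ cells alone had 100 with no CD34- peak. The contrast was smaller in lists of equal length. There, 3488 regions had a peak in all 4 libraries, 72.9% of 4786 CD34+ regions and 61.7% of 5657 CD34- regions. No peak of the other cell type was found at 11.3% of the CD34+ and 15.1% of the CD34- regions. Sites bound only in CD34- cells could count as shared if such cells were carried over into the CD34+ fraction, which was not tested.

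Other ways of pairing the 4 libraries gave fewer one-sided regions in total, 387 and 352 against 5057 for the split by cell type. The 4957 CD34- only regions carried that total, as only this split puts both longer lists on 1 side. Split by replicate number, 126 regions had peaks in both replicate 1 libraries only and 261 in both replicate 2 libraries only. The crossed pairs gave 313 and 39. The 100 CD34+ only regions were thus fewer than 126, 261 and 313 and more than 39. These raw counts are not alike, as CD34+ only regions must be missed by both longer lists. In shuffles chosen afterwards, independent misses within groups of strength predicted 9.86 CD34+ only and 4186 CD34- only regions. For the mixed pairs they predicted 76.6, 198, 272 and 33.3, in the order 126, 261, 313 and 39. With 3 splits no p-value under 0.333 can be reached, so none is given. In lists of equal length the counts were 855 regions in CD34- cells only and 542 in CD34+ cells only, 1397 together, against 620 and 456 for the other splits. Unequal noise between the cell types could give the same order, so the counts alone do not show a change of sites. Leaving out 1 library also moved these counts, since the cell type was then defined by its remaining library. Without CD34- replicate 1 the CD34- only count was 11755, and without CD34- replicate 2 it was 7576. The CD34+ only count was 411 without CD34+ replicate 1, 727 without CD34+ replicate 2 and 287 without CD34- replicate 2.

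**Figure D2:**
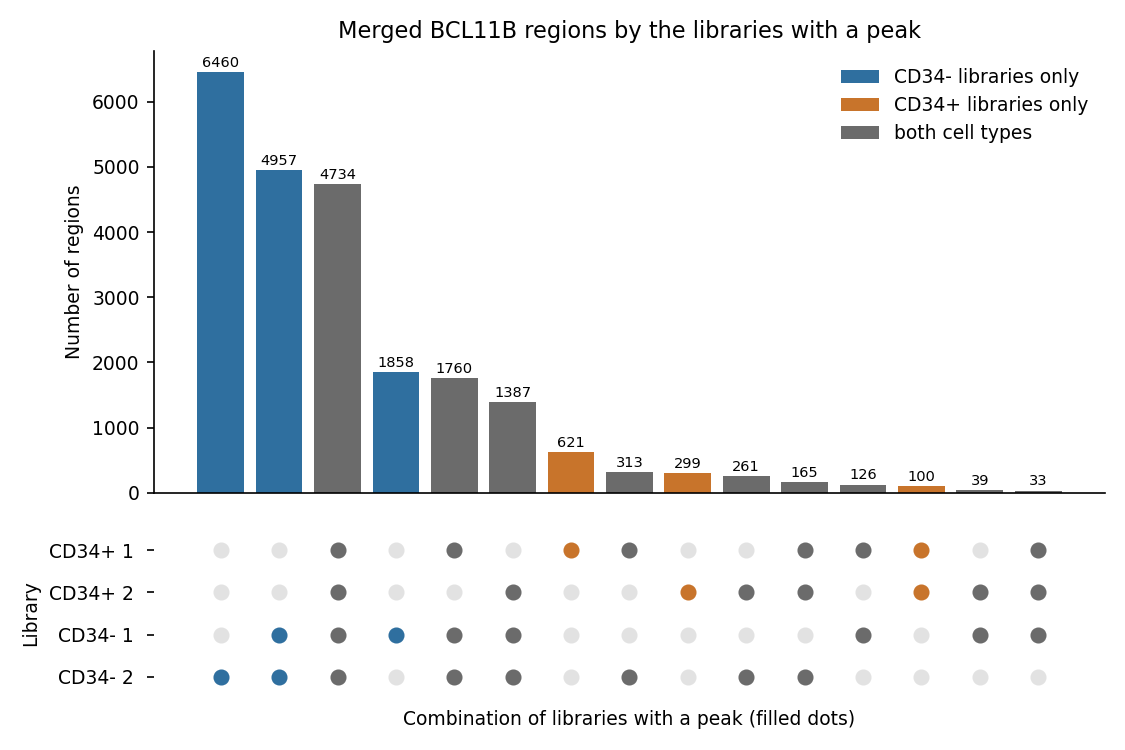
Number of merged regions (y axis) for each combination of libraries with a peak (x axis; filled dots mark the libraries). Regions in CD34- replicate 2 alone (6460), in both CD34- libraries only (4957) and in all 4 libraries (4734) were the most frequent, and 100 were in both CD34+ libraries only.

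Sites found in 1 library made up 9238 of the 23113 regions, or 39.97%. CD34- replicate 2 alone accounted for 6460 of them, CD34- replicate 1 for 1858, CD34+ replicate 1 for 621 and CD34+ replicate 2 for 299.

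CD34- regions without a CD34+ peak were mostly weak ones. In the weakest of 10 equal groups of CD34- regions, 80.8% (95% interval 78.6 to 83.0%) had no CD34+ peak and 3.505% had a peak in both CD34+ libraries. In the strongest group, 3.12% (2.24 to 4.22%; 40 of 1283 regions) had no CD34+ peak and 87.2% had both. That lowest share rose to 9.11% without CD34+ replicate 1, 6.86% without CD34+ replicate 2, 5.00% without CD34- replicate 1 and 7.37% without CD34- replicate 2. It was 5.07% with peaks of fold 6.40 or more. Leaving out a CD34+ library raises this share by construction, as a miss by the remaining library is then enough. Without a CD34- library, the remaining one alone defined the CD34- regions. Among CD34+ regions the share with no CD34- peak was 4.96% in the weakest group and 0.398% in the strongest (2 of 503).

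**Figure D3:**
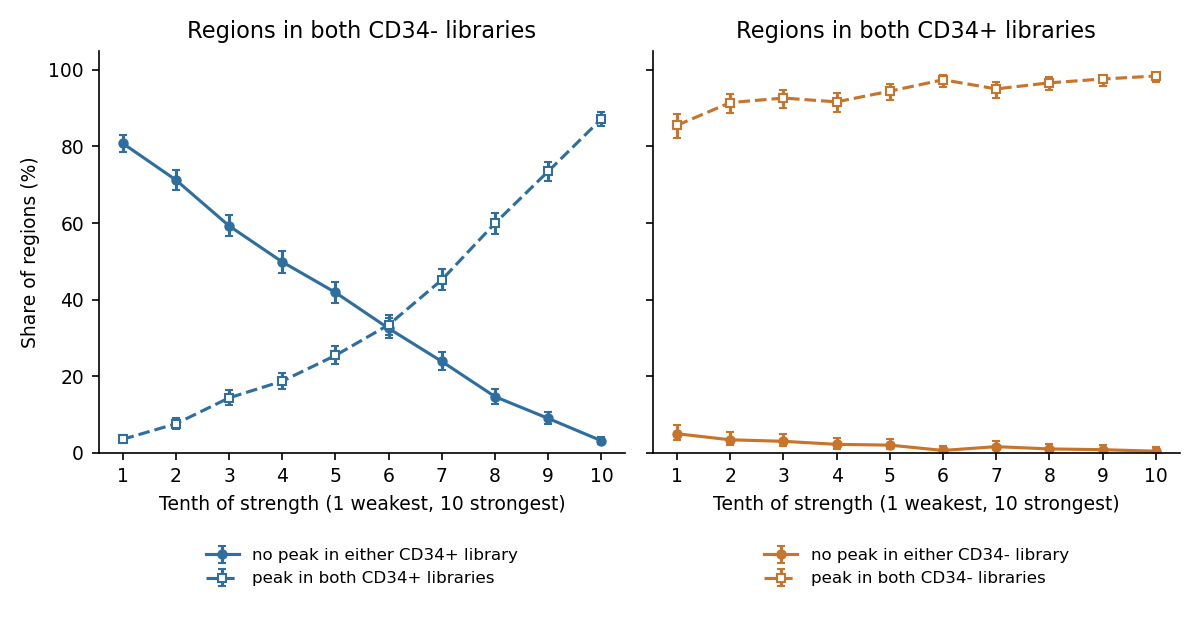
Share of reproducible regions (%, y axis) with no peak, or with peaks in both libraries, of the other cell type, by group of strength from 1 (weakest) to 10 (strongest; x axis), for CD34- regions (left) and CD34+ regions (right). Bars are exact 95% intervals, and the share of CD34- regions with no CD34+ peak falls from 80.8% to 3.12%.

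Within each list, peaks at shared regions were stronger and wider than peaks at regions of 1 cell type. Stronger and wider peaks meet a peak of another list more easily, so this direction follows in part from how the sets were defined. Each region entered with its strongest peak in that list. In CD34- replicate 1 the median −log10 q was 20.3 at the 4734 shared regions and 8.26 at the 4957 CD34- only regions. In CD34- replicate 2 these values were 31.8 and 10.8. Median widths were 781 against 365 bp in replicate 1 and 1021 against 502 bp in replicate 2. At the 100 CD34+ only regions the median −log10 q was 7.04 in CD34+ replicate 1 and 6.22 in CD34+ replicate 2, against 9.99 and 9.71 at shared regions. All 4 strength comparisons had a permutation p of 1e-05, the smallest that 100000 permutations can give. The same p was found for width in 3 lists, and in CD34+ replicate 1 the permutation p for width was 7e-05, with medians of 448 and 301.5 bp.

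At shared regions the signal was higher and broader in CD34- cells. The median summit pileup over the 4734 regions was 17 and 18 fragments in CD34+ replicates 1 and 2, and 27 and 42 in CD34- replicates 1 and 2. The summed peak width had a median of 482 and 446 bp in CD34+ cells and of 818 and 1035 bp in CD34- cells. Both CD34- libraries lay above both CD34+ libraries in each measure (two-sided exact permutation p = 0.333 for each, the smallest that 2 against 2 libraries allow). Summits stood close together. In the 3592 shared regions with 1 peak per library, the median distance was 33 bp between the CD34- replicates, 55 bp between the CD34+ replicates, and 40 to 55 bp across cell types.

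**Figure D4:**
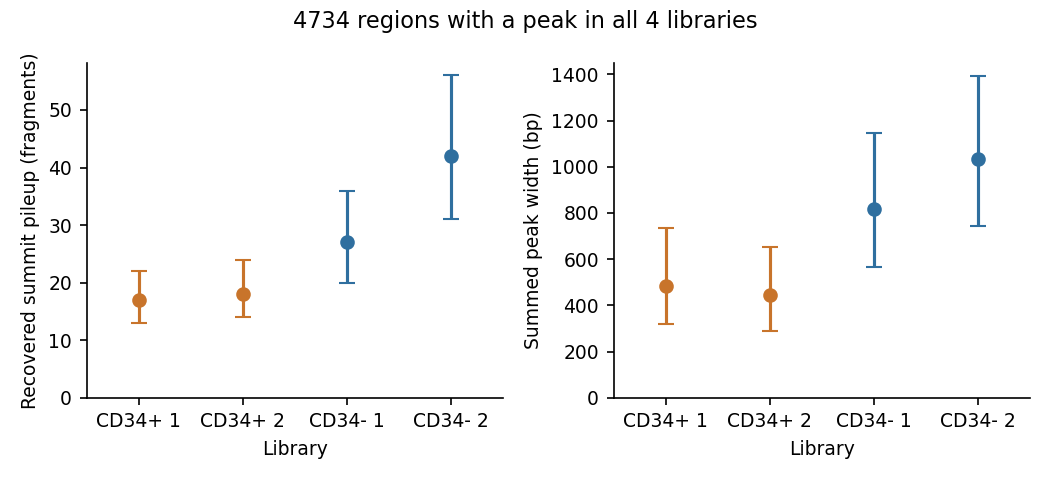
Summit pileup (fragments, left) and summed peak width (bp, right) in each library over the 4734 regions with a peak in all 4 libraries. Points are medians and bars span the lower to the upper quartile over regions, with medians of 17, 18, 27 and 42 fragments and of 482, 446, 818 and 1035 bp.

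The strongest shared regions differed in local background. At 5 of the 10, the local background was more than 10 times the genome background in at least 1 library. These were chr1:156186231-156186606, chr21:9825441-9827558, chr5:71146748-71146936, chr1:91852802-91853121 and chr20:26188713-26189359. No list of artefact regions was applied here, so whether these 5 are true binding sites was not tested. At chr1:156186231-156186606 the pileup was 1139 to 2370 fragments and the background 23.4 to 61.7 times that of the genome. The other 5 had backgrounds below 5 times that of the genome. The region chr19:49990272-49991283 had a fold of 32.3 to 73.7 in the 4 lists, and chr5:1499778-1504523 had 40.3 to 73.8. Folds at chr3:31573010-31575777 were 19.6 to 58.5, at chr6:33358972-33360106 22.9 to 38.0 and at chr4:48342652-48344421 23.9 to 34.0. When peaks wider than 5 kb or of very high pileup were removed, the 5 regions of high background and chr19:49990272-49991283 had no peak left. The regions at chr5:1499778-1504523 and chr3:31573010-31575777 then kept a peak in 2 libraries.

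Among CD34- only regions, chr9:29868681-29869910 ranked highest, with folds of 28.2 and 41.4 in the CD34- lists and a mean percentile of 99.4. Next came chr10:116304005-116304475 with folds of 26.2 and 27.0, and chr3:18932880-18934396 with 20.8 and 26.2. The others were chr19:16482032-16482791, chr4:153000683-153001790, chr1:227953834-227954627, chr8:135345091-135346151, chr15:70784720-70785777, chr2:28809393-28810539 and chr9:135698915-135700155. Mean percentiles of the 10 ran from 97.5 to 99.4, so they ranked among the strongest CD34- peaks.

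The 10 named CD34+ only regions came from a set of 100, against 4957 for CD34- only. Over each whole set the median percentile was 48.0 and 38.2 in CD34+ replicates 1 and 2, and 38.7 and 48.7 in CD34- replicates 1 and 2. The highest CD34+ only region, chr22:50166258-50166648, had folds of 15.9 and 19.7 and a mean percentile of 97.4. It was followed by chr16:50315823-50316247, with folds of 14.02 and 14.99 and a percentile of 94.8. Percentiles of the remaining 8 were between 78.2 and 86.0. These were chr16:814905-817396, chr1:234658396-234658690, chr9:140365208-140365524, chr7:98270940-98271682, chr15:72658301-72658588, chr15:75400663-75401380, chr2:129230824-129231180 and chr7:2738388-2739176. Neither CD34+ library showed a local background above 2.34 times its genome background at these 10 regions.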

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

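The alternatives for the region counts and overlaps left 54 of 69 values within 1.5 times the reported count or on the same side of the threshold. Not all of the 54 could have moved much. Leaving out a library of the other cell type gave 5033 and 5045 CD34+ and 12844 and 12838 CD34- regions. The overlap of CD34+ with CD34- replicate 2 fell from 93.5% to 72.0% in equal lists and still counted among the 54. The alternatives for high local backgrounds, for the share of the strongest CD34- regions and for windows were chosen after the data were seen. With a fold of at least 6.40, fewer peaks remained by construction, and the counts were 2374 regions reproducible in CD34+ cells, 7493 in CD34- cells and 2093 in all 4 libraries. With lists of equal length, which shortens 3 of the 4 lists, the counts were 5657 regions reproducible in CD34- cells, 855 in CD34- only and 542 in CD34+ only. Leaving out each library in turn gave 5033 to 7861 regions for CD34+ cells, with 7861 without CD34+ replicate 2, and 12838 to 20413 for CD34- cells, with 20413 without CD34- replicate 1. The ranges were 6343 to 11755 for CD34- only and 133 to 727 for CD34+ only, since 1 library then defined the cell type. For CD34- only the values outside 1.5 times were 11755 and 7576, without CD34- replicates 1 and 2. For CD34+ only they were 411 and 727 without CD34+ replicates 1 and 2, and 287 without CD34- replicate 2. The labels did not tie replicate numbers to thymuses, so whether equal numbers mark shared thymuses stays open, and they were not treated as pairs. The deviations of equally numbered libraries correlated at 0.209 over shared regions, which 2 replicates per cell type are too few to read as pairing. Counting within each replicate number as a block gave a mean of 10865.5 CD34- only regions (8241 and 13490) and 835 CD34+ only regions (1199 and 471). Those counts are larger by construction, as 1 library per cell type sufficed. In a test also chosen after the data were seen, the surplus of neighbouring CD34- only regions turned from 1.17 to 0.97 times the shuffled mean when pairs under 10 kb apart were left out. Removal of those close pairs shows where the surplus lay. Windows past the threshold fell from 2 to 1 when shifted by 100 kb. Of the 180 values for named regions, 171 kept their number of libraries. The 9 that did not were shared regions, 8 under removal of wide or very high peaks and 1 under the fold threshold. Named regions were picked as the strongest of their sets, so stricter thresholds and equal lists could hardly remove them. Nor can stricter thresholds add a peak of the other cell type. Random placement within gene spans, and the alternatives of the tests of gene location, gene lists and motifs, were not run. Depth was known only through the recovered genome background, so a peak missing from a list is one not detected at this depth.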

Other observations

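Each test of list length below was chosen after the lengths were seen. The window and chromosome counts were also chosen after the data were seen.

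Few of the windows tested held a surplus of CD34- only regions, and windows with fewer than 5 regions were not tested. In 564 windows of 200 kb with at least 5 reproducible CD34- regions, 2 held more CD34- only regions than their strength predicted, after Benjamini-Hochberg adjustment of an exact test. All 7 regions of chr14:52200001-52400000 were CD34- only against 2.40 predicted (exact adjusted p = 0.0138), and all 5 of chr22:18800001-19000000 against 1.34 (exact adjusted p = 0.0210). With windows shifted by 100 kb, only chr22:18700001-18900000 passed, with 6 of 6 against 1.43 (exact adjusted p = 0.00377), and the window at chr14:52100001-52300000 had 7 of 8 against 2.67 (exact adjusted p = 0.0665). At an unadjusted p under 0.05 there were 25 windows with more and 17 with fewer, and 26 and 25 with windows shifted. No window passed for fewer. The exact test of windows counted each region separately, so its p-values are too small where neighbouring regions depend on each other. The 5 regions of chr22:18800001-19000000 lay between positions 18876299 and 18894691, and their independence was not tested. None of the 22 autosomes passed Fisher's exact test for CD34- only against shared regions. The lowest exact p was 0.0100 on chromosome 19, with an odds ratio of 0.806 (adjusted p = 0.220).

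CD34- lists were longer than CD34+ lists, with a ratio of mean lengths of 2.26. The mean genome backgrounds, depth times fragment length, differed by 1.04 times, which argues against sequencing depth as the cause. Enrichment over background at shared regions was weaker in the CD34+ libraries, with median folds of 7.49 and 7.24 against 10.4 and 11.8 in CD34- libraries. A loss of weaker sites alone would not lower the signal at shared regions. Whether the weaker enrichment is technical or reflects binding was not tested. Of the strongest of 10 equal groups of CD34- regions, 3.12% had no CD34+ peak, against 80.8% of the weakest. Weaker enrichment and a real loss of weaker sites would both give these shares. In lists of equal length both CD34+ libraries missed the same CD34- regions 1.65 times as often as independent misses within groups of strength predict (855 against a shuffled maximum of 568), and both CD34- libraries missed the same CD34+ regions 2.19 times as often (542 against 294). Pairings that mix the cell types gave at most 1.59 times, a difference of 0.0682 (bootstrap 95% interval −0.0841 to 0.210) for CD34- regions and 0.604 (0.416 to 0.787) for CD34+ regions. In the whole lists, which differ in length, the ratio was 1.18 for CD34- regions, below the highest mixed pairing of 1.64. For CD34+ regions it was 10.1 there (100 against a shuffled maximum of 21). No simulation was matched to the whole lists. In 20 simulations with normally distributed strengths and noise alone, matched to the overlap of replicates, the mean ratio was 1.198 for CD34- regions, 1.80 for CD34+ regions and 1.45 for the highest mixed pairing, so noise alone also puts CD34+ regions above mixed pairings. All 3 observed ratios in lists of equal length exceeded the highest simulated ones, 1.27, 1.89 and 1.51. Exponentially distributed strengths gave nearly the same, 1.23, 1.88 and 1.496. The simulated overlap across cell types, averaged over its pairs, had a mean of 69.1% (68.2 to 69.5%). Observed values of 63.7%, 64.5% and 65.9% lay below this range, which goes against noise alone as simulated. The observed 68.8%, between CD34+ and CD34- replicates 2, lay within it, and no observed value lay above it. The simulated range is of means over the pairs, so a single pair within it does not show agreement. As the simulation fell short for mixed pairings too, it did not describe these libraries fully, and a change of ranks cannot be told apart from noise here. These comparisons replaced one of the one-sided counts, 1397 against 620 and 456, and the intervals and simulations were added after the ratios were seen. Cell type itself stays open and untested, as do the 19000000 to 29000000 CD34+ cells used per library against 60000000 CD34- cells. Carry-over of CD34- cells into the CD34+ fraction, whose purity is known only as a lower bound, was not tested either and stays open.

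CD34- only regions lay next to each other more often than shuffling within 10 groups of strength gave. Of 5913 neighbouring pairs up to 50 kb apart, 1115 were both CD34- only, above the highest of 10000 shuffles within 10 groups of strength, 1033 (permutation p = 0.0001, the smallest they can give). The shuffles held strength fixed only within these 10 groups. Regions of like strength lying together at a finer scale are therefore not excluded. Among pairs 10 to 50 kb apart, 478 of 3420 were both CD34- only against a shuffled mean of 491.7 and a maximum of 564 (permutation p = 0.787). The surplus may thus come from broad signal broken into several regions under 10 kb apart. A change of binding over short domains in CD34- cells was not tested and stays open.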
